A study of Schizosaccharomyces pombe with 66 samples.

How the data were processed

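Cells were grown in EMM with supplements at 30 °C unless noted, per the labels' protocols. Rad52 with a CFP-TAP tag was precipitated with IgG Sepharose, Rad52 with a FLAG tag in the HO strain with anti-FLAG antibody, Rad52-YFP with GFP-Trap and Rpa1 with a TAP tag with IgG Sepharose, per the labels. DNA was denatured at 95 °C, ligated to adaptors with random hexamer ends, selected by gel for lengths of 250 to 500 bp, and amplified by 25 cycles of PCR before sequencing with an Illumina GA-II, per the labels' protocols. CASAVA is the only processing tool named, without a version, per the submitters' processing notes. The aligner, its treatment of reads with several matches and the genome build are not given in the sources used here. Groups follow the sample titles. No genotype is given in the labels of the hst4_cdc25 libraries of 90 min and of the asynchronous culture or of the slm9 library, and their groups rest on the titles.

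Values are signed counts of reads as deposited, with a track line per the file headers and no other description of the unit in them. From the values, each entry is a whole number of reads whose 5' end lies at a position, positive for the forward and negative for the reverse strand, not divided by depth and with duplicates kept. Reads starting at one position on one strand may be PCR copies, so each result was repeated with 1 read per position and strand. Positions were placed on assembly ASM294v3, and the fit of this build was checked. In 27 of 27 segments of up to 500 kb the base bias at read starts was strongest on the reference without an offset, among offsets of up to 4000 bp. So it was in 14 of 15 pieces of 10 kb at the right ends of the chromosomes, while the last piece of chromosome III, in rDNA, gave no clear offset. Reads extend past the reference, to 4542844 on chromosome II, whose reference ends at 4539804, and the 35 to 5499 reads per library beyond the ends lie in no window. Reads of the mitochondrial genome were left out of shares of nuclear reads and of the windows.

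Reads were summed over both strands in windows of 1 kb with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. The count test fixed before the data were examined was not run, since the signed values were classed as unit other. Instead, limma voom was used (limma 3.58.1 in R 4.3.3). The sums per window are whole numbers of reads, so the values do not exclude a count test. Windows with a mean of at least 5 reads per library were kept. Libraries were scaled by TMM, computed here with trims of 0.3 of the log ratios and 0.05 of the averages. One fit held the 18 Rad52-CFP-TAP IP libraries of 7 conditions with replicates, and another the IP and input libraries of WT_hminus and hst4. Windows were called at an adjusted p under 0.05 (Benjamini-Hochberg), and CPM are reads scaled to the library size after TMM. For pfh1, no paired analysis was possible because the labels give no pairs of libraries across temperatures. In an alternative fit with the pfh1 allele as a term, 15 named regions kept the call and 0 lost it. In the pfh1 comparison the 4 nonpermissive libraries include both alleles, 1 library with SPATRNAVAL.01 replaced and 1 with a potential origin replaced, both of these labelled h+ and the other pfh1 libraries h-.

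The following were chosen before the data were examined: the comparisons, windows, filter, scaling, threshold, locus classes, flanks of arg3 and mat1, the rule for named regions and the alternatives other than the added ones. The locus classes, from the annotation of the reference, are tRNA genes, 5S rRNA genes, rDNA, Tf2 elements, solo LTRs, centromeres, subtelomeres (outer 50 kb), snRNA and snoRNA genes, ribosomal protein genes, core histone genes, strongly expressed Pol II genes, wtf genes, mug genes and the mating-type region. Each class was tested with camera of limma with a preset correlation of 0.01 between windows, and again with the correlation estimated from the data. Added after the data were seen were voom with library quality weights, limma-trend, the pfh1 comparison without both libraries with a replaced locus, strand shares at Tf2, rDNA, centromeres, tRNA genes, 5S rRNA genes and long regions, the tRNA windows inside and outside centromeres, and the rDNA and centromere shares of the time course. Called windows less than 2 kb apart were merged, and the 15 higher and 5 lower regions with the largest log2 fold change of their strongest window were named by the genes that this window overlaps. Fixed items were named as well. One named region of the hst4 comparison is not reported here.

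Around a site, the facing share is the share of reverse reads on the left and forward reads on the right within 10 kb, or 3 kb for sets of genes with 1 read per position and strand. Shares have exact binomial (Clopper-Pearson) 95% intervals. Deleted genes were checked by the reads inside the coding region after leaving out 20% at each end. The test was tested on simulated data with 50 windows for each of 4 fold changes. For hst4 it found 47 of 50 windows raised 4-fold and 27 of 50 lowered to 0.25, with 0 false calls, and 3 of 50 raised 2-fold. For histone.D1.D3 it found 49 and 47 of 50 with 0 false calls, for pfh1 42 and 40 with 2 false calls, and for ams2 27 and 26 with 49 false calls, so changes of 2-fold are mostly missed.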

Results

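Rad52, the recombination mediator encoded by rad22 in fission yeast, was immunoprecipitated from haploid cells and the co-purified DNA was sequenced so that the strand of each single-stranded molecule was kept. The 66 libraries comprised 48 IP libraries and 18 input libraries in 55 groups. Of these groups, 46 held 1 library, 7 held 2 and 2 held 3, so a test against the spread between libraries was possible for 7 comparisons. The series asks which genomic sites are vulnerable in mutants with raised genome instability. Each file lists positions with a signed read count, positive for the forward and negative for the reverse strand. Total reads ranged from 177509 in the smt0 input to 3378447 in replicate 3 of the histone.D1.D3 IP group, with a median of 733798. The number of reads per occupied position and strand ranged from 1.05 to 8.98. It was highest in replicate 1 of ams2 IP (8.98), followed by replicate 3 of histone.D1.D3 IP (6.18) and replicate 2 of ams2 IP (6.15). The WT_hminus IP libraries had 1.34 and 1.74. Duplicates also weigh on the WT_hminus input libraries, the control of WT_hminus IP against input. Between these inputs the chi-square per degree of freedom was 8.54 with all reads and 1.08 with 1 read per position and strand. Mitochondrial DNA made up 0.190% to 39.3% of all reads, with the highest share in replicate 2 of the hst4 input group. Replicates 1 and 2 of the hst4_Rad52_YFP IP group agree within sampling noise once reads at the same position and strand are counted once (chi-square per degree of freedom 0.969), and they were counted as 1 sample. Positions are given on assembly ASM294v3, since the sources used here name no build.

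The deleted genes were examined first, since reads inside a deleted gene test the labels. The inner coding region of hst4, the gene of a sirtuin-family histone H3 lysine 56 deacetylase, held 0 reads in each of the 3 hst4 IP libraries and in both hst4 input libraries, against 43 and 42 reads in the WT_hminus IP libraries. The inner coding region of cbp1, whose CENP-B-like product restrains Tf2 retrotransposons, held 0 reads in both cbp1 IP libraries against 64 and 81 in WT_hminus. Reads of ams2, the gene of a GATA-type activator of histone genes, numbered 0 and 8 in the ams2 IP libraries against 52 and 86. The swi1, swi3, mus7, slm9 and rtt109 genes each held between 0 and 5 reads in the libraries named for their loss. In the hst4_cdc25 libraries hst4 held between 0 and 3 reads, except 8 reads at 1 position at 80 min and 9 reads at 3 positions in the asynchronous library, at 23.7% and 31.0% of the mean WT_hminus IP density. Labels and reads differed most in the rtt109_hst4 pair. In the libraries labelled rtt109_hst4, hst4 held 31 reads in the IP and 31 in the input, at 108% and 163% of the mean WT_hminus IP density, and rtt109 held 31 and 28 reads. The same libraries had 0 reads in crb2 and 0 in his3, neither of which is deleted in the label. The coding region of crb2 ends at 4213423 on chromosome II, beside that of rtt109, which starts at 4213640. In 19 libraries, this pair among them, his3 held under 15% of its median density over all libraries. Of the pair labelled hst4_histoneD1D3, the IP library had 0 reads in hst4, hht1 and hhf1 and 6 and 5 reads in hht3 and hhf3, while the input library had 3 reads each in hst4, hht1 and hhf1 and 9 and 4 in hht3 and hhf3. These groups are therefore called by what they are labelled, and no direction is drawn from their names.

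A break made by the HO endonuclease at arg3 shows how Rad52 reads lie around a known double-strand break. In the HO IP library, reads on the left of arg3 (chromosome I, 2273921 to 2275516) came almost entirely from the reverse strand and reads on the right from the forward strand. Within 10 kb on the left, 86373 reads were reverse and 59 forward, a reverse share of 99.93% (95% interval 99.91 to 99.95), and within 10 kb on the right 71822 were forward and 189 reverse (99.74%, 99.70 to 99.77). Reads on these facing strands made up 99.84% of the 158443 reads at the site, and the site held 27.4% of all nuclear reads (27.3 to 27.5). The HO input library had a facing share of 92.7% (90.4 to 94.6) with 0.175% of nuclear reads (0.161 to 0.189) there. In WT_hplus IP, which carries no HO site, the facing share was 46.4% (42.2 to 50.5) with 0.143% of nuclear reads. Each of these groups is 1 library, and the exact Clopper-Pearson intervals here and in the other single libraries cover counting error only. Because the 10 kb on each side took 27.4% of the HO IP reads, shares of other loci in that library are lowered by at least that. Farther out the same strands still prevailed. The HO IP library had 530 reverse and 16 forward reads at 2233001 to 2234000. At 2314001 to 2315000 it had 101 forward and 5 reverse reads.

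**Figure D1:**
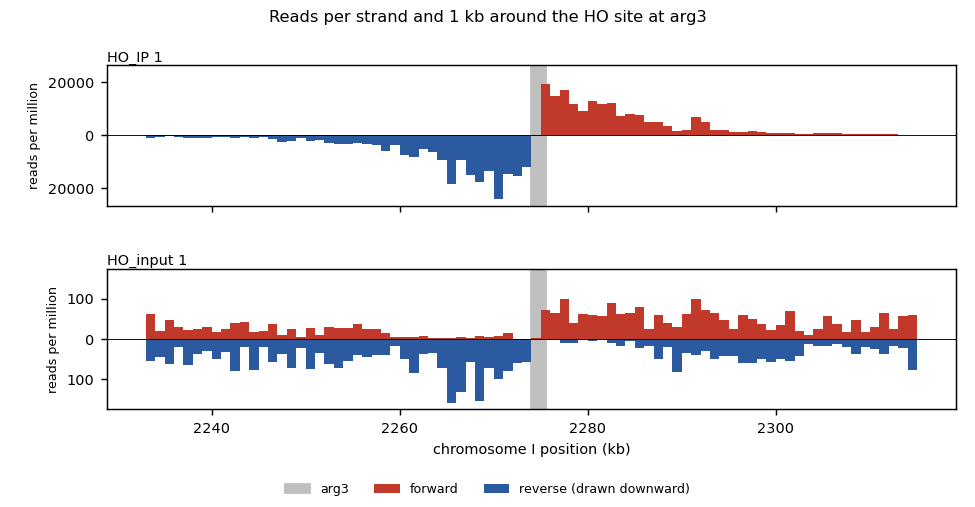
RPM (reads scaled to nuclear reads) on the forward strand (up) and reverse strand (down) in 1 kb bins against chromosome I position in kb, for the HO IP and HO input libraries, with arg3 shaded and a separate vertical scale per library. In the HO IP library 99.93% of the reads within 10 kb left of arg3 are reverse and 99.74% of those on the right are forward.

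The mating-type cassettes mat1, where an imprint on one strand starts mating-type switching, and mat3, a silent donor, were the sites most enriched in WT_hminus Rad52 DNA. At mat1-Mc (chromosome II, region 2110001 to 2116000) the strongest window had 4758 ± 1109 CPM (SD, n = 2) in WT_hminus IP and 173 ± 17.6 CPM (n = 2) in WT_hminus input, a log2 fold change of 4.77 (SE 0.39, adjusted p = 7.7e-07, limma), higher in 2 of 2 IP libraries. The silent cassette mat3-Mc (2132001 to 2135000), whose sequence nearly repeats that of mat1-Mc, rose by 4.84 (SE 0.36, adjusted p = 3.6e-07, limma), so reads cannot be assigned to one of these copies with certainty. Of the 30 windows of the mating-type region 11 rose, or 22 when adjusted over the list alone, with a median log2 fold change of 1.34 (camera adjusted p = 7.6e-30, and adjusted p = 0.0507 with an estimated correlation). Other named sites include short Pol III genes, with SPATRNAPRO.01 up by 2.09, SPATRNAARG.01 by 1.89 and the 5S gene SPRRNA.10 by 1.73 on the log2 scale. They also include the non-coding mamRNA (1.90) and the protein-coding genes nvj2 (1.87), cdc24 (1.81), tuf1 (1.74), thi2 (1.74), eng1 (1.73), rpl4301 (1.67) and sof1 (1.67). These sites outside the mating-type region are calls of single windows, and with repeated loci left out limma called 0 windows, while 1811 had an unadjusted p under 0.05. Beside mat1 the strands faced each other as at the HO break, with facing shares of 72.3% (71.5 to 73.1) and 68.5% (67.5 to 69.4) in the WT_hminus IP libraries and 29.5% and 31.8% in the WT_hminus input libraries. In smt0, whose deletion beside mat1 removes the imprint, the facing share was 42.0% (37.0 to 47.1) with 0.133% of nuclear reads beside mat1, against 1.29% and 0.887% in WT_hminus IP. In WT_hplus IP the facing share was 34.6% (31.0 to 38.4) with 0.159% of nuclear reads.

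**Figure D2:**
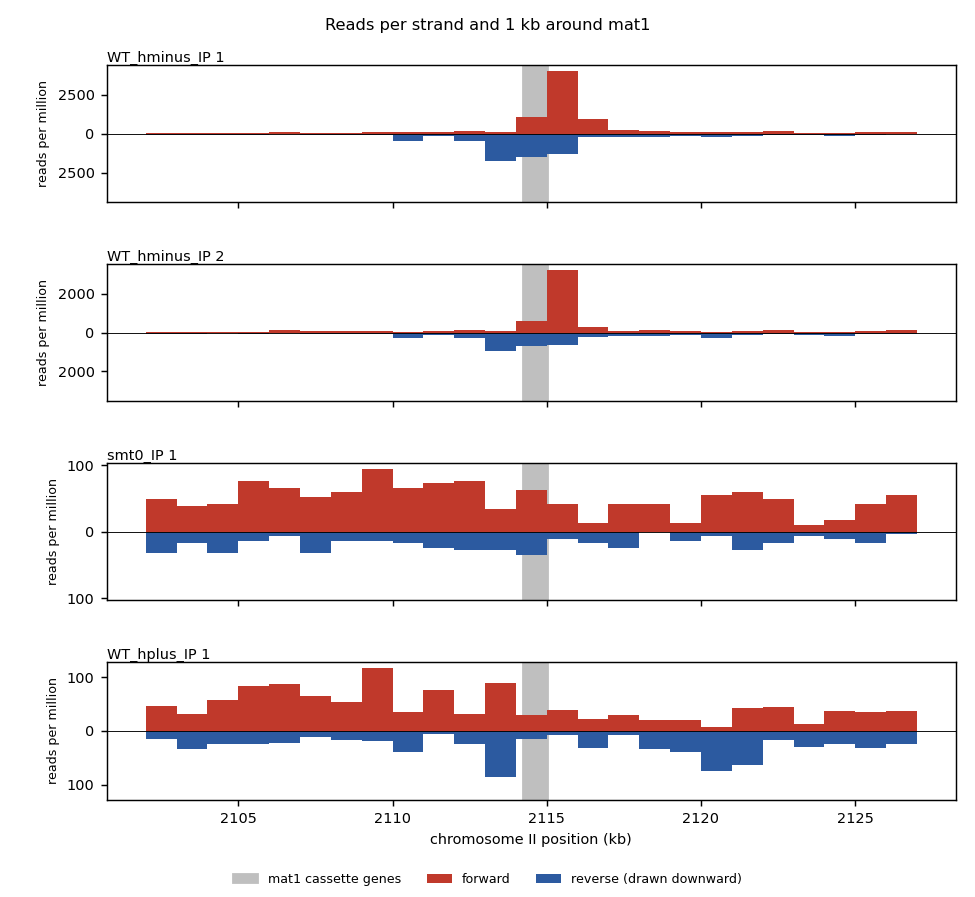
RPM (reads scaled to nuclear reads) on the forward strand (up) and reverse strand (down) in 1 kb bins against chromosome II position in kb, for both WT_hminus IP libraries and for the smt0 and WT_hplus IP libraries, with the mat1 cassette genes shaded and a separate vertical scale per library. The peak at mat1 in WT_hminus IP, with 1.29% and 0.887% of nuclear reads within 10 kb, is not seen in smt0 (0.133%) or WT_hplus (0.159%).

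Other gene classes in WT_hminus IP against input were described with the lists fixed before the data were examined. Windows of tRNA genes had a median log2 fold change of 0.62, with 4 of 157 called higher, or 61 when adjusted over the list alone (camera adjusted p = 2.9e-24, and adjusted p = 0.058 with an estimated correlation). Windows of snRNA and snoRNA genes had a median of 0.60 and 0 of 74 called, or 22 higher and 1 lower when adjusted over the list alone (camera adjusted p = 1.5e-13, and 0.0313 with an estimated correlation). Ribosomal protein genes had a median of 0.44 with 1 of 220 called higher, or 17 over the list alone (camera adjusted p = 1.9e-13, and 0.0271 with an estimated correlation). Medians were also above 0 for 5S rRNA genes (0.73, 2 of 41 windows called, 19 higher and 1 lower over the list alone), core histone genes (0.65, none of 13 called) and strongly expressed Pol II genes (0.71, 1 of 49 called, 15 higher and 1 lower over the list alone), and below 0 for subtelomeres (-0.41) and centromeres (-0.22). These 5 lists passed camera and lost the call with an estimated correlation, with adjusted p = 0.0671, 0.124, 0.124, 0.0745 and 0.26 in the same order. The rDNA median was 0.34 with all reads, with no window called, and -1.19 with 1 read per position and strand. In replicate 1 of WT_hminus IP the rDNA held 48392 reads on the strand of the rRNA genes. That is more than the positions on 1 strand of its 37 windows of 1 kb. Counting 1 read per position caps such counts, so the second value cannot decide the direction, which stays open. Over all windows 31 of 12572 were called by limma, 29 higher and 2 lower, and 1920 had an unadjusted p under 0.05. This count fell to 5 without WT_hminus_IP replicate 1 and 9 without WT_hminus_IP replicate 2, and was 1016 without WT_hminus_input replicate 1 and 342 without WT_hminus_input replicate 2. On simulated data 18.75% of the calls of this comparison were false, 30 beside 130 true ones. The real data gave only 31 calls, so the false share there can be higher. All calls of single windows outside the mating-type region may be false.

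In hst4 cells, which lack Hst4, the Rad52 profile differed over long chromosome regions. In hst4 IP against WT_hminus IP, 1553 windows rose and 631 fell of 12573 tested by limma. The windows that rose merged into 325 regions covering 1768 kb, of which 46 were at least 10 kb long, and the longest spanned 59 kb. The region with the largest rise lay on chromosome II from 894001 to 946000. Its strongest window, in num1, the gene of a cortical dynein anchor, had 263 ± 15.1 CPM (SD, n = 3) against 44.4 ± 1.29 CPM (n = 2) in WT_hminus. The log2 fold change was 2.55 (SE 0.31, adjusted p = 0.000152, limma). The same region includes swi1, the gene of a replication fork protection protein, with 8 of 8 windows higher and a strongest log2 fold change of 2.51. Each of the 15 named regions was higher in 3 of 3 hst4 libraries than in both WT_hminus libraries.

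The other named regions that rose in hst4 had log2 fold changes from 2.13 to 2.46. On chromosome II they include the mmm1 and mis19 region (1312001 to 1324000), the dni2 region (1161001 to 1198000), the ppk31 region (1203001 to 1237000), the region of clr6, a histone deacetylase gene (847001 to 861000), the adl1 region (863001 to 883000), the apc13 region (1831001 to 1862000) and the region of gcn2, an eIF2-alpha kinase gene (2384001 to 2404000). On chromosome I they include pby1 (4567001 to 4606000), mug191 (2044001 to 2081000), lon1, a mitochondrial protease gene (681001 to 702000) and cdc123 (1610001 to 1661000). On chromosome III they include sec59 (851001 to 862000) and a region of non-coding genes from 120001 to 135000. The 229 windows of mug genes, named for induction in meiosis, held 34 that rose and 4 that fell, or 33 and 4 when adjusted over the list alone, but the class as a whole was not called (limma camera, adjusted p = 0.441). Neither was the class of wtf genes, a family of meiotic drivers, with 1 of 60 windows higher and 0 over the list alone (limma camera, adjusted p = 0.387), nor the mating-type region with 1 of 30 windows lower (limma camera, adjusted p = 0.293).

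The windows that fell in hst4 include the whole rDNA. All 37 rDNA windows fell, with a median log2 fold change of -2.97 (limma camera, adjusted p = 1.5e-35, and adjusted p = 0.0551 with an estimated correlation), and the share of nuclear reads in rDNA was 1.43% ± 0.435 (SD, n = 3) against 10.1% ± 0.782 (n = 2) in WT_hminus IP. In the hst4 input libraries that share was 6.56% ± 0.563 (n = 2), against 8.83% ± 0.738 (n = 2) in WT_hminus input. Ribosomal protein genes had 45 of 220 windows lower and 4 higher, or 61 and 5 when adjusted over the list alone, with a median of -0.83 (camera adjusted p = 4.5e-11, and 0.0134 with an estimated correlation). The snRNA and snoRNA genes had 19 of 74 windows lower and 1 higher, or 26 and 3 over the list alone, with a median of -0.85 (camera adjusted p = 2.0e-07, and 0.0104 with an estimated correlation). Medians were -0.90 for tRNA genes (39 of 157 windows lower, 1 higher), -0.78 for 5S rRNA genes (7 of 41 lower), -0.91 for centromeres (27 of 169 lower), -1.17 for subtelomeres (23 of 202 lower), -1.03 for core histone genes (4 of 13 lower) and -1.49 for strongly expressed Pol II genes (20 of 49 lower). Adjusted over the list alone, 54, 10, 24, 13, 7 and 28 windows of these classes were lower, and 3 windows of tRNA genes were higher. Of the 39 tRNA windows that fell, 14 lie within the centromeres. These 6 classes passed camera and lost the call with an estimated correlation, with adjusted p = 0.323, 0.331, 0.323, 0.206, 0.189 and 0.127 in the same order. Solo LTRs had 14 windows higher and 10 lower of 262 (12 and 8 over the list alone, median -0.29, adjusted p = 0.368 with an estimated correlation), and the Tf2 median of 0.45 held no called window (adjusted p = 0.645 with an estimated correlation). Single regions that fell include prl53 on chromosome I (-3.32) and pho84, a phosphate transporter gene, on chromosome II (-3.17). At mat1-Mc 1 of 2 windows fell, by 2.95 on the log2 scale (adjusted p = 0.00318, limma). The count of 2184 windows was 606 without WT_hminus_IP replicate 1, 485 without WT_hminus_IP replicate 2, and 1310, 1167 and 1380 without hst4_IP replicate 1, 2 and 3. The split of higher and lower windows also moved, from 1553 and 631 to 3106 and 2891 with library quality weights and to 374 and 480 with limma-trend, so the ratio of higher to lower windows depends on the method.

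Against its own input, hst4 Rad52 DNA was enriched over swi1, clr6 and the mating-type region. The region from 887001 to 946000 on chromosome II reached a log2 fold change of 2.61 and all 8 swi1 windows rose, by up to 2.54. The region of clr6 (847001 to 885000) reached 2.73, that of dni2 2.71 and mat3-Mc 2.63 (SE 0.33, adjusted p = 0.000384, limma, 3 of 3 libraries). The mating-type region had 18 of 30 windows higher, or 26 over the list alone, with a median of 1.28 (camera adjusted p = 1.1e-16, and adjusted p = 0.124 with an estimated correlation). Centromeres fell, with 126 of 169 windows lower, or 155 over the list alone, and a median of -1.38 (camera adjusted p = 1.4e-40, and 0.0117 with an estimated correlation). Subtelomeres fell too, with 152 of 201 windows lower, or 180 over the list alone, and a median of -1.65 (camera adjusted p = 7.9e-47, and 0.0124 with an estimated correlation). All 37 rDNA windows fell (median -2.19, adjusted p = 0.105 with an estimated correlation). Solo LTRs had 45 windows lower and 5 higher (46 and 7 over the list alone), tRNA genes 24 lower, 22 of them within the centromeres, and 2 higher (26 and 4) and ribosomal protein genes 18 lower and 8 higher (16 and 8), with adjusted p = 0.241, 0.447 and 0.241 with an estimated correlation. The Tf2 median was 0.54 (1 window higher, 0 over the list alone) and that of strongly expressed Pol II genes -0.40 (1 lower, 0 over the list alone), with adjusted p = 0.291 and 0.567 with an estimated correlation. In all, limma called 946 windows higher and 910 lower of 12572. That total of 1856 was 2 without hst4_input replicate 2, 69 without hst4_input replicate 1, 235 without hst4_IP replicate 3 and 738 without hst4_IP replicate 2. It was 234 with a replicate block, 1200 with repeated loci left out, 4168 with 1 read per position and strand, 3955 with library quality weights and 3908 with limma-trend. Replicate 2 of the input had 39.3% mitochondrial reads.

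The regions that rose in hst4 were examined in the other libraries, and in some without Hst4 their share was far below that of hst4 IP. The 1553 windows are 12.4% of all windows and held 24.1% ± 1.58 of nuclear reads (SD, n = 3) in hst4 IP, in which they were chosen, against 8.84% ± 0.0733 (n = 2) in WT_hminus IP. They held 20.5% and 20.8% in the hst4_Rad52_YFP IP libraries, where Rad52 carries another tag, and 19.90% (19.82 to 19.99) in hst4_Rpa1 IP, where the largest subunit of the single-strand binding protein RPA was precipitated. The matched inputs held 9.66% and 9.57%. The share was 14.4% (14.3 to 14.5) in swi1 IP and 16.9% (16.8 to 17.0) in swi3 IP, which lack parts of the fork protection complex but keep hst4, against 10.01% and 10.996% in their inputs. In hst4_mus7 IP, which also lacks the Mms22-like repair protein Mus7, the share was 8.70% (8.65 to 8.75), against 10.2% in its input. Of the nuclear reads outside rDNA and Tf2 it was 10.5% in hst4_mus7 IP and 11.2% in its input, as rDNA takes 16.4% of that IP library. Shares were 7.72% (7.67 to 7.77) in hst4_H3K56A IP, 8.66% (8.59 to 8.73) in hst4_H3K56Q IP and 7.99% (7.94 to 8.04) in hst4_H3K56R IP, where lysine 56 of histone H3 is replaced and, per the labels, the hht1-hhf1 and hht3-hhf3 gene pairs are deleted. As Tf2 takes many reads of these 3 libraries, the share was also taken of nuclear reads outside rDNA and Tf2, where it was 10.1%, 10.6% and 11.4% against 9.88% and 9.89% in WT_hminus IP. The share in rtt109 IP, which lacks the lysine 56 acetyltransferase, was 10.95% (10.84 to 11.07) against 11.5% in its input. The IP libraries labelled rtt109_hst4 and hst4_histoneD1D3 had 10.7% (10.6 to 10.8) and 23.4% (23.3 to 23.5).

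In the hst4_cdc25 time course, with cdc25-22 as a heat-sensitive allele that holds cells before mitosis, the share of these windows was 11.01% at 0 min and 10.2% at 50 min. It was 12.0% at 60 min, 16.2% at 80 min, 21.02% at 100 min and 25.2% (25.0 to 25.3) at 130 min. In the asynchronous hst4_cdc25 library it was 13.7% (13.67 to 13.83), against 24.1% in hst4 IP. The rDNA share was 7.33% at 0 min, 11.4% at 50 min, 1.56% at 80 min, 4.34% at 120 min and 3.27% at 130 min, and the centromere share was 0.893% at 0 min and 0.192% at 130 min. Mitochondrial DNA made up 11.9% of reads at 0 min, 13.4% at 50 min and 2.65% at 130 min. Each time is 1 library, and the labels used here give no genotype for the libraries of 90 min and of the asynchronous culture.

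**Figure D3:**
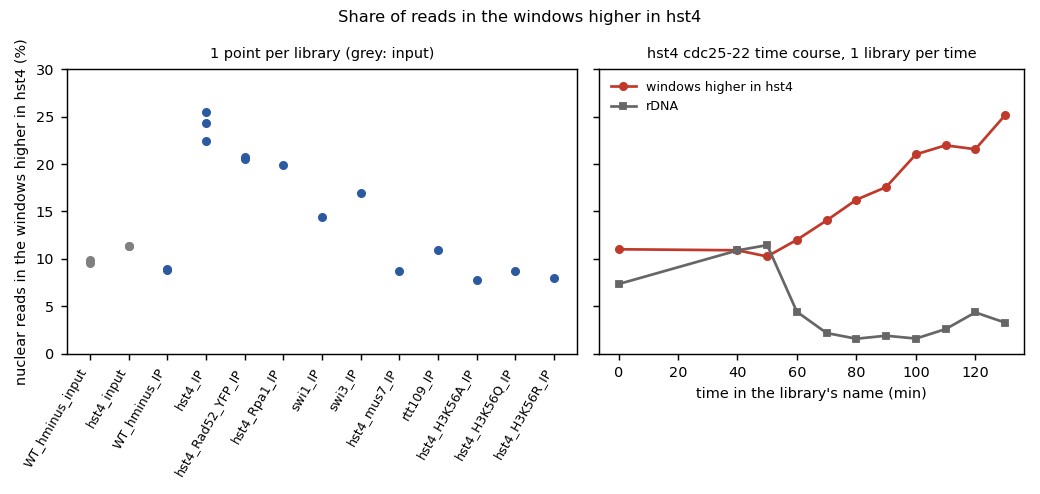
Left, the percentage of nuclear reads in the 1553 windows that rose in hst4, 1 point per library, for groups with input libraries in grey. Right, that percentage and the rDNA percentage against the time in the library's name in min, 1 library per time, where the first runs from 11.01% at 0 min to 25.2% at 130 min and the second from 7.33% to 3.27%.

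In the histone.D1.D3 strain, which lacks the histone H3-H4 gene pairs hht1-hhf1 and hht3-hhf3, Rad52 DNA was enriched for the retrotransposon Tf2. The 13 full-length Tf2 elements held 21.8% ± 2.85 of nuclear reads (SD, n = 3) in histone.D1.D3 IP against 0.415% ± 0.0186 (n = 2) in WT_hminus IP, and 0.499% (0.485 to 0.512) in the single histone.D1.D3 input library. All 64 Tf2 windows rose, also when adjusted over the list alone, with a median log2 fold change of 5.95 (adjusted p = 6.1e-05 with an estimated correlation). The strongest window, in Tf2-6 (chromosome I, 4022001 to 4027000), had 7638 ± 1913 CPM (n = 3) against 64.0 ± 6.06 CPM (n = 2), a log2 fold change of 6.87 (SE 0.48, adjusted p = 4.3e-09, limma), and the other elements ranged from 6.40 in Tf2-3 to 6.80 in Tf2-4. The elements are nearly identical in sequence, so the reads of any one copy are uncertain, and how reads with several matches were counted is not given in the sources used here. The reads lay on the coding strand, with sense shares of 98.4% (98.3 to 98.4), 97.5% (97.5 to 97.6) and 96.2% (96.1 to 96.2) in the 3 IP libraries, against 20.3% and 18.5% in WT_hminus IP. These are strands of reads. Within 10 kb of the HO break, reads were 99.93% reverse on the left and 99.74% forward on the right. Those are the complements of the strands whose 3' ends lie at the break. If Rad52 bound those strands, the Tf2 reads would likewise be the complement of the bound DNA. Which strand was bound was not tested here.

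Most other calls in histone.D1.D3 lie in windows of repeated loci. A region of chromosome I from 2939001 to 2943000 with the non-coding genes SPNCRNA.3329 and SPNCRNA.3330 rose by 6.05, and a window of nse1, a subunit gene of the Smc5-Smc6 complex, by 3.52 on the log2 scale, and both lie among the windows of repeated loci. With those windows left out limma called 3 of 11987 windows, 1 higher on chromosome III between 254001 and 256000 and 2 lower at the deleted gene pairs. Solo LTRs had 33 of 262 windows higher, or 49 over the list alone (camera adjusted p = 1.7e-08, and adjusted p = 0.0534 with an estimated correlation). All 3 windows that fell lie in the deleted gene pairs, hht1-hhf1 by 3.42 (SE 0.50, adjusted p = 0.000215, limma) and hht3-hhf3 by 2.99 (SE 0.49, adjusted p = 0.000888, limma), each lower in 3 of 3 libraries. Other classes moved little. Medians were -0.31 for snRNA and snoRNA genes and -0.24 for ribosomal protein genes, with no window called and adjusted p = 0.00804 and 0.0291 with an estimated correlation. Medians were -0.22 for tRNA genes, -0.11 for subtelomeres (0.17 with 1 read per position and strand) and -0.76 for the mating-type region, with no window called and adjusted p = 0.811, 0.898 and 0.811 with an estimated correlation. Core histone genes were called lower by camera from their 3 lower windows, while their median was 0.01 (adjusted p = 0.089 with an estimated correlation). In all, limma called 104 windows higher and 3 lower. Replicate 1 differs from replicates 2 and 3 in its labelled genotype at hhf2 and at a marked Tf2-12 element, so the 3 libraries are not of one strain.

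Libraries of related strains differed in the Tf2 share. The share was 0.477% (0.464 to 0.491) in histone.D1 IP and 0.354% (0.341 to 0.367) in histone.D3 IP, which each lack 1 gene pair, close to the 0.415% of WT_hminus IP. It was 16.3% (16.2 to 16.4) in hst4_H3K56A IP, 8.17% (8.10 to 8.24) in hst4_H3K56Q IP and 20.4% (20.3 to 20.5) in hst4_H3K56R IP, all of which lack both pairs per the labels, with sense shares of 94.1%, 89.4% and 98.0%. The H3K56A and H3K56R inputs held 0.553% and 0.537%. In hst4_H3K56Q IP the hht3 gene held 3 reads, at 16.6% of the mean WT_hminus IP density. The library labelled hst4_histoneD1D3 had 0.826% (0.808 to 0.844). In slm9 IP, which lacks a HIRA-type histone chaperone subunit, the share was 3.70% (3.65 to 3.76), and in rtt109 IP it was 1.60% (1.56 to 1.65) against 0.389% in the rtt109 input. In WT_hplus IP it was 0.822% (0.794 to 0.850), so shares under about 1% also occur without a histone mutation. The strands of these reads differed too. Sense shares were 82.1% in slm9 IP, 84.1% in rtt109 IP and 69.3% in the IP library labelled hst4_histoneD1D3. They were 56.1% in WT_hplus IP, 40.1% in histone.D1 IP and 30.1% in histone.D3 IP. Of the 28 IP groups with 1 library outside pfh1, 19 had a share whose interval lay above both WT_hminus IP libraries. The 28 groups include 11 times of the hst4_cdc25 course, with shares of up to 0.550%, so they are not separate strains.

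**Figure D4:**
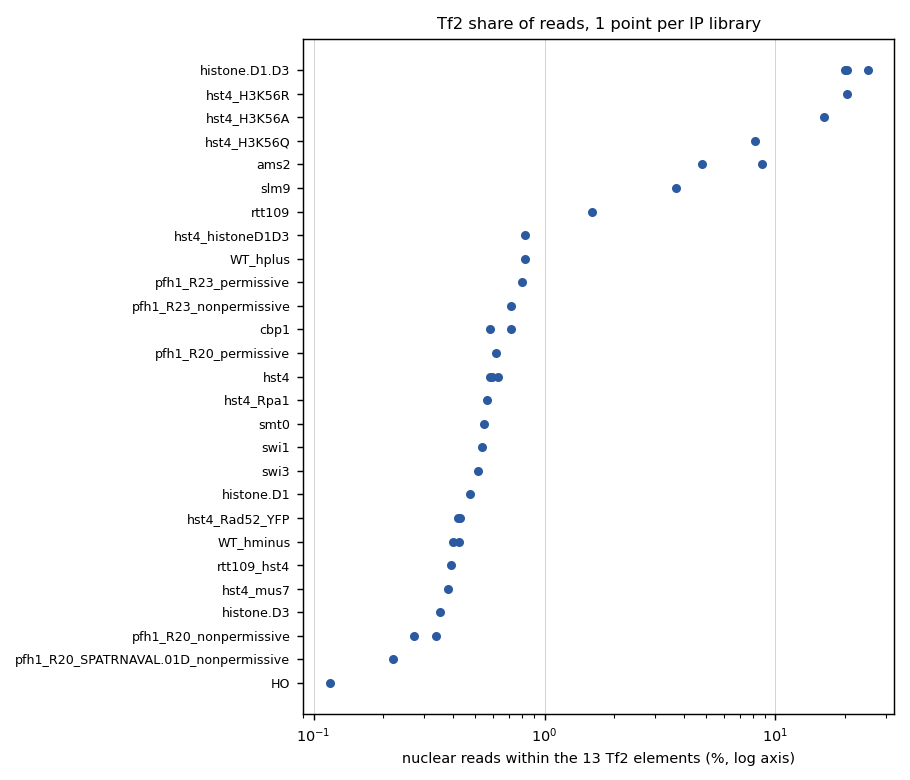
Percentage of nuclear reads within the 13 Tf2 elements on a log axis, 1 point per IP library, ordered by group. The 3 histone.D1.D3 libraries (19.9%, 25.0% and 20.3%) and the 3 H3K56 mutant libraries (8.17% to 20.4%) lie far above the WT_hminus libraries (0.428% and 0.402%).

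In ams2 cells, which lack the histone gene activator Ams2, Rad52 reads rose at the same element class. The Tf2 share was 6.78% ± 2.76 (SD, n = 2) in ams2 IP, and all 64 Tf2 windows rose, also over the list alone, with a median log2 fold change of 4.33 (limma camera, adjusted p = 1.2e-113, and 0.0282 with an estimated correlation). Sense shares were 77.1% and 75.8%. The window with the largest rise was not in Tf2. It overlapped pof2, an F-box protein gene, and mot1, the gene of a TBP-removing ATPase (chromosome II, 2618001 to 2620000). It had 3019 ± 820 CPM (n = 2) against 70.4 ± 13.1 CPM (n = 2), a log2 fold change of 5.39 (SE 0.58, adjusted p = 7.1e-06, limma). Tf2-5 followed with 5.26 and the other named regions of Tf2 with 4.36 to 5.06. SPNCRNA.3329 on chromosome I rose by 4.50 and a non-coding region of chromosome II from 3489001 by 2.65. Solo LTRs had 43 of 262 windows higher, or 64 higher and 7 lower over the list alone (camera adjusted p = 0.000416, and adjusted p = 0.266 with an estimated correlation).

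The remaining classes were less affected by ams2. The 5S rRNA genes had 1 window higher, or 2 higher and 1 lower over the list alone (median 0.48, adjusted p = 0.728 with an estimated correlation), ribosomal protein genes 3 lower (also over the list alone, median -0.23, adjusted p = 0.273) and the snRNA and snoRNA genes none (median -0.35, adjusted p = 0.236), each a class that passed camera with the preset correlation. Windows that fell include those of nup120 and rtt106, a nucleoporin and a histone chaperone gene, with 0 reads in both ams2 libraries against 46.5 and 42.4 CPM in WT_hminus IP, where 3 occupied positions with the mean number of reads would be 26.4 and 29.7 CPM in the ams2 libraries. In all, limma called 172 windows higher and 17 lower, and 2762 had an unadjusted p under 0.05. The ams2 libraries had 8.98 and 6.15 reads per occupied position, and on simulated data 43.75% of the calls in this comparison were false. The 189 calls were 741 without ams2_IP replicate 1, 474 without ams2_IP replicate 2 and 104 without either WT_hminus_IP replicate, and were 68 with library quality weights. With repeated loci left out 44 windows were higher and 83 lower, so which direction prevails depends on the repeats.

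In cbp1 no window passed the test against WT_hminus IP. The cbp1 libraries had Tf2 shares of 0.716% (0.684 to 0.749) and 0.580% (0.554 to 0.606), and Tf2 windows had a median log2 fold change of 0.74. At mat1-Mc the strongest window had 352 CPM against 3950 CPM in WT_hminus IP, a log2 fold change of -3.46 (SE 0.63, adjusted p = 0.281, limma). Beside mat1 the cbp1 libraries held 0.253% and 0.239% of nuclear reads, with facing shares of 47.5% and 46.0%. These values lie nearer to smt0 and WT_hplus IP than to WT_hminus IP. Whether the mating type of the strain or the loss of cbp1 lies behind them was not tested. The mating-type region had a median of -1.72, with 8 of 30 windows lower when adjusted over the list alone. Camera with the preset correlation called that region lower (adjusted p = 1.6e-26) and Tf2 (2.9e-16), centromeres (2.9e-10, median 0.40, 1 window higher over the list alone) and strongly expressed Pol II genes (0.000177, median 0.48) higher. It called 5S rRNA genes (1.3e-06, median -0.52), tRNA genes (0.009, median -0.14) and snRNA and snoRNA genes (0.0319, median -0.11) lower. With an estimated correlation none of these 7 classes was called, with adjusted p = 0.201, 0.468, 0.516, 0.468, 0.468, 0.728 and 0.318 in the same order. The limma voom fit called 0 of 12573 windows, while 524 had an unadjusted p under 0.05, limma-trend called 1 and voom with library quality weights 63. These libraries were among the smaller ones, with 268921 and 329393 reads, and on simulated data the test found 31 of 50 windows raised by 4-fold and 8 of 50 lowered to 0.25.

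In cells with thermosensitive alleles of pfh1, the gene of a Pif1-family DNA helicase that acts in nuclear and mitochondrial DNA, Rad52 reads at centromeres rose at the nonpermissive temperature. Libraries of the alleles R20 and R23 at that temperature were compared with those at the permissive temperature. No library of cells with wild-type pfh1 at the nonpermissive temperature was analysed here, so an effect of temperature is not separated from one of Pfh1. Centromere windows rose in 148 of 169 cases, or 166 over the list alone, with a median log2 fold change of 1.76 (camera adjusted p = 4.9e-122, and 0.017 with an estimated correlation). The largest change lay beside the centromere of chromosome II (region 1556001 to 1622000), where the strongest window, in hrd3, a gene of endoplasmic reticulum protein degradation, had 876 ± 329 CPM (SD, n = 4) against 109 ± 64.4 CPM (n = 2), a log2 fold change of 3.03 (SE 0.52, adjusted p = 0.00319, limma), higher in 4 of 4 libraries. On chromosome III a region of 95 kb (1046001 to 1141000) over the centromere reached 2.53, and on chromosome I the region 3753001 to 3790000 with SPATRNAILE.03 reached 2.50.

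Calls at tRNA genes in pfh1 lie mostly within the centromeres. Windows of tRNA genes rose in 34 of 157 cases, or 57 over the list alone, with a median of 0.74 (camera adjusted p = 2.2e-27, and adjusted p = 0.342 with an estimated correlation). Of these, 29 lie among the 35 tRNA windows of the centromeres and 5 among the 122 outside them, or 7 over that list alone, where the median was 0.58 (limma camera, p = 3.6e-14, and p = 0.117 with an estimated correlation). The 5S rRNA windows rose in 3 of 41 cases, or 8 over the list alone (median 0.74, camera adjusted p = 6.0e-10, and adjusted p = 0.457 with an estimated correlation). Arm regions named by the rule include rar1 (2.20) and sec31 with tim50 (2.13) on chromosome II, iba57 (2.04) on chromosome I, and the 5S gene SPRRNA.05 (2.19), mto1 (2.03), dbp6 (2.03) and gst1 (1.97) on chromosome III. Strongly expressed Pol II genes had a median of 0.32 with 1 window higher (0 over the list alone), while medians were -0.65 for Tf2, -0.37 for subtelomeres and -1.08 for the mating-type region, which had 0 windows called and 10 lower over the list alone. Replicate 2 of pfh1_R20 nonpermissive and the SPATRNAVAL.01 library are labelled h+ and the other pfh1 libraries h-, so at the mating-type region temperature is mixed with mating type. These 4 classes passed camera and had adjusted p = 0.55, 0.55, 0.55 and 0.509 with an estimated correlation. In all, limma called 421 windows higher and 0 lower, and 1615 had an unadjusted p under 0.05. At 5 kb windows 157 of 2515 were higher and 26 lower, so the absence of lower calls rests on the window size. The limma-trend fit called 136 windows and voom with library quality weights 498. The 421 calls were 0 without pfh1_R23_permissive_IP replicate 1, 716 without pfh1_R23_nonpermissive_IP replicate 1, 262 without pfh1_R20_nonpermissive_IP replicate 1 and 233 without pfh1_R20_permissive_IP replicate 1.

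Strands at the centromeres of chromosomes II and III faced each other at the nonpermissive temperature. Beside the centromere of chromosome II the facing shares within 10 kb were 94.8% and 94.6% in the pfh1_R20 nonpermissive libraries, 94.3% in the library with SPATRNAVAL.01 replaced and 90.1% in pfh1_R23 nonpermissive, against 73.5% and 65.5% in the permissive libraries of these alleles and 36.6% and 34.4% in WT_hminus IP. For chromosome III the 4 nonpermissive libraries had 91.8%, 92.1%, 88.0% and 85.6% in the same order, the permissive libraries 72.0% and 59.6% and WT_hminus IP 34.4% and 38.4%. For chromosome I the nonpermissive libraries differed, with 80.5%, 59.1%, 48.9% and 81.3%, against 44.4% and 50.3% in the permissive libraries and 34.1% and 35.4% in WT_hminus IP. At the tRNA gene SPATRNAVAL.01 (chromosome I, 446000 to 446071), the reverse share on the left side was 93.9% (93.1 to 94.6) and 95.7% (94.6 to 96.7) in the pfh1_R20 nonpermissive libraries. It was 75.7% (72.6 to 78.7) in pfh1_R23 nonpermissive, 61.4% (54.4 to 68.0) in the pfh1_R20 nonpermissive library where this gene had been replaced by ura4, 79.0% (76.5 to 81.4) in pfh1_R20 permissive, 48.7% (44.6 to 52.7) in pfh1_R23 permissive and 41.9% and 44.8% in WT_hminus IP. Neither of the 2 windows at SPATRNAVAL.01 passed the test between temperatures (stronger window, log2 fold change 1.18, SE 0.50, adjusted p = 0.308, limma), in which 1 of the 4 nonpermissive libraries lacks this gene. At SPBTRNAGLN.01 and SPBTRNAGLN.03, which flank a potential origin replaced in replicate 2 of pfh1_R20 nonpermissive, the log2 fold changes were 1.01 and 0.82 with no call.

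**Figure D5:**
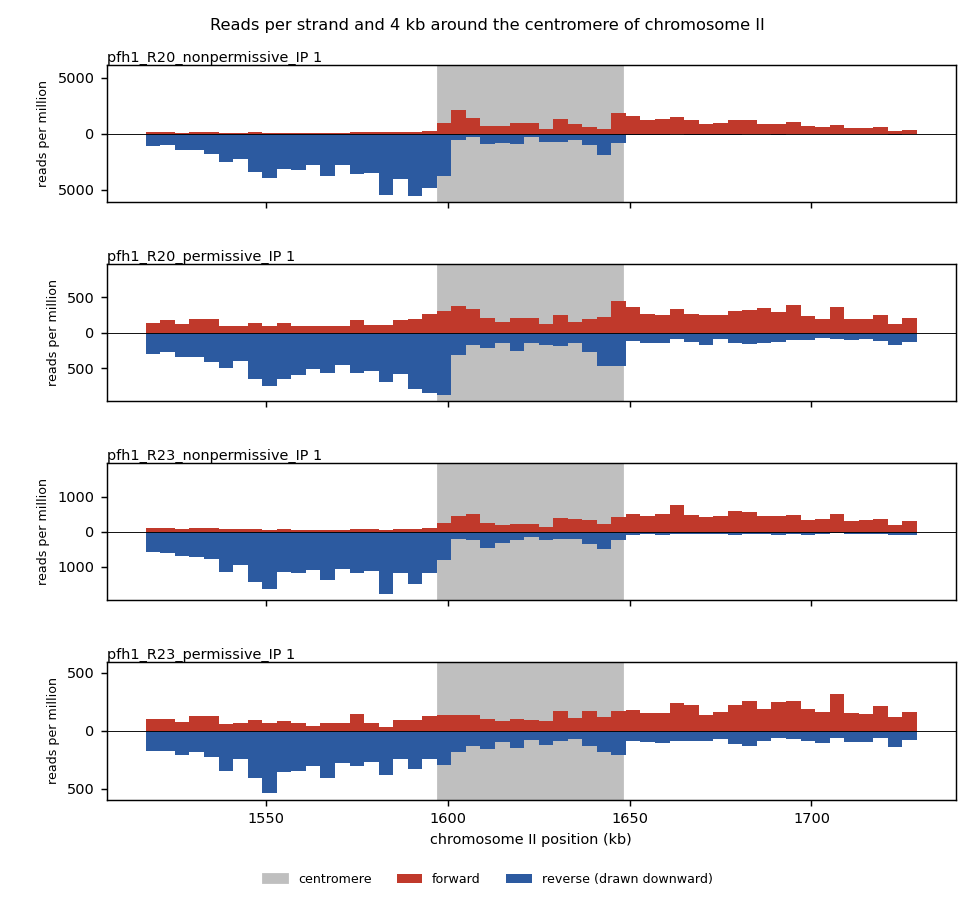
RPM (reads scaled to nuclear reads) on the forward strand (up) and reverse strand (down) in 4 kb bins against chromosome II position in kb around the centromere (shaded), for 1 library per pfh1 allele and temperature, with a separate vertical scale per library. Reverse reads on the left and forward reads on the right make up 94.8% in pfh1_R20 nonpermissive replicate 1 and 90.1% in pfh1_R23 nonpermissive within 10 kb of the centromere.

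The p-values in all 7 comparisons measure only the spread between these libraries, since the labels do not say whether replicates are separate cultures. Libraries that the labels place in groups of 1 were described by their shares, without a test. Comparisons with WT_hminus IP use the same 2 control libraries, so their calls are not independent of each other.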

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

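The tests of Tf2 copies, duplicate reads, DNA amount, mixture and label below were chosen only after the result was seen, while those of the Tf2 flanks and of the reads outside rDNA were written before their values were known.

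The Tf2 share rose in all 3 histone.D1.D3 IP libraries. More Tf2 copies in the genome are unlikely, since double-stranded copies would give a strand share near that of WT_hminus IP, while the lowest sense share of the 3 libraries was 96.2% and the 1 input library held 1.14 times the WT_hminus input share. Duplicate reads are unlikely too, because with 1 read per position and strand the share was 8.85 to 19.6 times the WT_hminus IP mean. Rad52 on the chromosomal copies with their flanks is also unlikely, as the 1 kb outside the elements and their LTRs held 0.876 to 0.885 times the WT_hminus IP mean. Single-stranded Tf2 DNA bound by Rad52 after loss of the histone gene pairs stays open as a hypothesis.

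Long regions rose in hst4 IP. More DNA of these regions in hst4 cells is unlikely, as the hst4 inputs held 1.17 times the share of the WT_hminus inputs. Fewer rDNA reads in the hst4 libraries could raise all other shares. Outside rDNA and Tf2 the ratio of hst4 to WT_hminus IP was 2.49, against 2.72 with all nuclear reads. The fall from 2.72 to 2.49 shows how far rDNA and Tf2 reads move the ratio. That the ratio stays raised cannot by itself count against this explanation, as the windows were called higher in these same libraries after scaling. The size of the rDNA share does argue against it. In no library did rDNA hold more than 16.4% of nuclear reads. Loss of all such reads would raise other shares far less than 2.72 times. An effect of the loss of Hst4 stays open as a hypothesis.

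In the libraries labelled rtt109_hst4 the genes hst4 and rtt109 had reads. A mixture with DNA of other strains is unlikely, as the density of crb2 was 0% of the WT_hminus IP mean in the IP and the input. A wrong label remains possible. The lowest density of hst4 or rtt109 in either library was 108% of the WT_hminus IP mean. These densities argue against DNA from cells that lack both genes, in the IP and the input. They restate the reads that raised the question, so they cannot show how label and DNA came to differ. No biological explanation was tested.

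Other results met a rule set in advance and are given without explanation. By Dixon's test among the 4 pfh1 nonpermissive libraries, pfh1_R23_nonpermissive_IP replicate 1 stood apart in its mitochondrial share of 0.845%. By the same test it stood apart in the share of nuclear reads within 10 kb of mat1, 1.68%, where the pfh1_R23 permissive library had 2.19%. It is the only library of allele R23 among the 4. For each single quantity chance alone gives a flag in about 1 in 20 such tests. As 9 quantities were examined, at least 1 flag by chance is likelier than that. In a limma test of the difference of IP over input between hst4 and WT_hminus, 699 windows were called, 326 higher and 373 lower. Outside the planned measures, the share of rDNA reads on the strand of the rRNA genes was 75.48% in hst4_H3K56A IP, 81.19% in hst4_H3K56R IP and 91.69% in hst4_mus7 IP, above the 52.2% to 70.8% of the 18 inputs.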

How the results depend on the processing

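Library quality weights, limma-trend and the pfh1 comparison without both libraries with a replaced locus were chosen only after the result was seen. Of 1412 values of the 109 named regions under alternatives, 1230 were the same, 182 lost the call and 0 turned direction. Without pfh1_R23_permissive replicate 1 all 15 pfh1 regions lost the call, without hst4_input replicate 2 19 of 20 regions of hst4 IP against input, and without both libraries with a replaced locus 9 of 15. Of 68 other values 33 were the same and 35 moved. DESeq2 size factors and its Wald test were not run, and the median-of-ratios scaling was computed here, with 2256 windows for hst4. Replicate numbers showed no pairing (correlations -0.0769 to 0.095).

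Windows for hst4 IP against WT_hminus IP (2184) were 3710 with 1 read per position and strand, 1200 at 5 kb, 5997 with quality weights, 854 with limma-trend, 5873 with only the 2 groups in the fit and 699 as a difference of IP over input. They were 485 without WT_hminus_IP replicate 2 and 1380 without hst4_IP replicate 3. For histone.D1.D3 (107) they were 25 at 5 kb and 3 with repeated loci left out. For ams2 (189) they were 444 with 1 read per position and strand, 54 at 5 kb, 68 with quality weights, 298 with limma-trend, 104 without WT_hminus_IP replicate 1 and 741 without ams2_IP replicate 1. For cbp1 (0 by limma voom, 524 at an unadjusted p under 0.05) they were 1 with 1 read per position and strand, 1 at 5 kb, 1 with repeated loci left out, 1 with limma-trend, 63 with quality weights and 3 with a replicate block. For pfh1 (421) they were 183 at 5 kb, 136 with limma-trend, 0 without pfh1_R23_permissive_IP replicate 1 and 716 without pfh1_R23_nonpermissive_IP replicate 1. For WT_hminus IP against input (31) they were 489 with 1 read per position and strand, 0 with repeated loci left out, 18 with quality weights, 5 without WT_hminus_IP replicate 1 and 1016 without WT_hminus_input replicate 1. For hst4 IP against input (1856) they were 4168 with 1 read per position and strand, 1200 with repeated loci left out, 3955 with quality weights, 3908 with limma-trend, 234 with a replicate block, 2 without hst4_input replicate 2 and 1447 without hst4_IP replicate 1.

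Class calls numbered 57, and 11 with an estimated correlation. The facing share at arg3 in HO IP (99.84%) was 99.86% with a 5 kb flank and 98.71% with 1 read per position and strand. At mat1 those values were 76.4% and 64.5% in WT_hminus_IP replicate 1 and 76.1% and 58.2% in replicate 2.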

Other observations

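All strand shares in this part were chosen only after the result was seen, and none was tested. Pol III genes in pfh1 R20 had strands that faced each other. At the 36 5S rRNA genes the facing shares were 64.0% and 65.7% in the pfh1_R20 nonpermissive libraries and 65.2% in the library with SPATRNAVAL.01 replaced, against 51.6% in pfh1_R23 nonpermissive, 55.4% in pfh1_R20 permissive and 48.9% and 48.7% in WT_hminus IP. At the 118 tRNA genes on chromosome arms they were 61.7% (61.4 to 62.1) and 60.4% (59.4 to 61.3) in pfh1_R20 nonpermissive, 50.8% in pfh1_R23 nonpermissive and 46.9% and 46.8% in WT_hminus IP. In the hst4 cdc25-22 time course the arm tRNA genes had 46.3% at 0 min, 37.2% at 60 min and 47.8% at 130 min. Beside mat1 the facing share was 91.3% in replicate 2 of pfh1_R20 nonpermissive and 91.9% in the SPATRNAVAL.01 library, both labelled h+, and 87.3%, 85.6%, 66.7% and 60.2% in the h- libraries of pfh1_R23 nonpermissive, pfh1_R23 permissive, pfh1_R20 permissive and replicate 1 of pfh1_R20 nonpermissive, against 34.6% in WT_hplus IP.

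In the 46 regions of at least 10 kb that rose in hst4, reverse reads made up 55.1%, 54.7% and 54.0% on the left of the middle and forward reads 59.2%, 59.4% and 59.3% on the right in the hst4 IP libraries. The swi1 and swi3 IP libraries had 52.7% and 52.7% on the left and 59.2% and 59.7% on the right, hst4_Rpa1 IP 54.0% and 57.7%, and the WT_hminus IP libraries 49.8% and 50.5% on the left and 50.6% and 49.9% on the right. In hst4_mus7 IP the rDNA held 16.4% (16.3 to 16.4) of nuclear reads, against 8.25% in its input. At the rDNA the swi1 and swi3 IP libraries had 10.3% and 8.57% against 4.01% and 3.71% in their inputs.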
